A study of Mus musculus with 16 samples.

How the data were processed

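Total RNA of 16 plates of mouse embryonic fibroblasts was hybridised to Affymetrix whole-transcript expression arrays, 1 array per plate: control and Atf5-knockdown cells, each with vehicle or with 1 µM MG132 for 8 h, n = 4 per group. Groups and replicate numbers were taken from the sample titles. The labels describe separate plates and do not say that they came from separate cultures or days, so p-values measure only the spread between these samples, which may be technical.

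The values deposited by the authors are log2 probe set intensities rounded to 2 decimals. RMA and Partek are named in the submitters' processing notes, and their versions and settings, the background correction among them, are not given in the sources used here. The quartiles of the arrays were nearly equal (medians 7.71 to 7.82), so the deposited log2 values appear scaled to each other, and 0 of the 35556 by 16 values were missing. RMA equalises array distributions, so a change of most genes in 1 direction would be hidden. Changes of dim and of very bright probe sets can be compressed on arrays. No detection calls were used here, so no statement is made that a gene is absent.

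Probe sets were named through the platform's annotation table. Of the 35556 probe sets 23410 were listed there and 12146 were not, 1621 carried several gene symbols and 21789 carried 1. Of the last, 21698 matched the RefSeq gene table of assembly GRCm38.p6 by gene ID, which changed 0 symbols. That table served only for names and for which chromosome a gene lies on, and no coordinates are printed, since the build of the array's design is not given in the sources used here. Probe sets with several symbols or none were left out of the gene tests. For 999 genes with several probe sets the one with the highest mean over all 16 arrays was used, which left 19938 genes. Probe sets of 1 gene had calls of opposite sign in 11, 5, 10, 9 and 1 genes in the 5 comparisons in the order of the results.

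A linear model with a mean for each of the 4 groups was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 12 residual and 4.12 prior degrees of freedom), with no filter on dim probe sets and no block. The 5 contrasts were: MG132 minus vehicle in control cells, the same in knockdown cells, knockdown minus control with vehicle and with MG132, and the difference of the MG132 responses. Adjusted p-values are Benjamini-Hochberg values over all genes tested unless stated otherwise, with a threshold of 0.05. The fit was tested on simulated data in which 200 of 19938 genes had been changed. At 1.25-fold 74.6% were recovered in the control response, 71.6% in the knockdown response, 79.1% and 79.1% in the line comparisons and 47.8% in the difference of the responses. At 1.5-fold these were 98.5%, 97.0%, 98.5%, 97.0% and 91.0%, with 6, 5, 6, 12 and 12 unchanged genes called. The simulated noise was independent between genes, and far fewer genes were changed than were called in the data. These rates therefore check the fit and may not carry over to the real arrays.

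The gene lists, 18 of pathways and 8 of cell type markers, written before the data were examined, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a kind within a comparison, and with camera at a correlation estimated from the data and fry beside it. With the estimated correlation 9, 9, 2, 2 and 0 pathway lists passed in the 5 comparisons. List members were counted over all genes tested and also adjusted over the list alone. The named genes follow a rule of the same date: per comparison the 10 highest and 10 lowest log2 fold changes past the threshold without overlap of the arrays (for the difference of the responses, past the threshold), skipping gene models, clones and small RNAs, up to 4 members of each list with the smallest p, and a panel of 12 stress genes. Of that panel Cdkn1a is not among the genes tested. Single values of 4 against 4 arrays were compared with an exact two-sided permutation test.

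Alternatives were a second quantile normalization, centring on array medians, filters at the 25th percentile and at a mean of 6, all probe sets, the mean of a gene's probe sets, only the groups compared, no moderation, a trended robust prior, array weights, a 1.5-fold minimum, the replicate number as a block and leaving out each array. After the data were seen, leaving out 4 arrays toward the low end of the within-group gradient (also with knockdown MG132 2 in place of control vehicle 4, almost level with it) and that gradient as a covariate were added. The gradient is the first principal component of the deviations of these same arrays from their group means. As a covariate it leaves the fold changes as they are and takes out spread, which favours more gene calls. Genes it adds are therefore no independent support. Python 3.11.15 with matplotlib 3.10.9 drew the figures.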

Results

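Expression was measured on 16 microarrays of total RNA from mouse embryonic fibroblasts, connective tissue cells grown in culture. The cells were of 2 kinds: a control line, given as wild type with a scramble short hairpin RNA, and a line stably expressing a short hairpin RNA against Atf5, a transcription factor of the ATF/CREB family. Each line was kept for 8 h in vehicle (DMSO) or in 1 µM MG132, a peptide aldehyde that inhibits the proteasome, with 4 plates per group. The table held 35556 probe sets, of which 19938 genes were compared. Array medians lay between 7.71 and 7.82 on the log2 scale, and the number of arrays, not read depth, limits the precision. Arrays of the same group correlated at r = 0.9969 to 0.9992 and arrays of different groups at 0.9774 to 0.9941, across probe sets. The first principal component, with 61.9% of the variance, separated the lines, and the second, with 24.6%, separated MG132 from vehicle. A gradient inside the groups took 37.8% of the within-group variance. Markers of macrophages, endothelium, epithelium, skeletal muscle, smooth muscle, adipocytes and neurons were higher at its low end (median r over each list -0.303 to -0.694), and fibroblast markers were lower there (0.321). Pathway lists followed it too, from 0.522 (p53 targets) and 0.483 (mitosis) to -0.285 (BCL2 family). Control MG132 4 and knockdown vehicle 1, at the low end, had the highest medians over named genes of their groups (8.18 and 8.24). Their 75th percentiles over all probe sets were the lowest (10.01 and 10.07). Whether the gradient reflects a mixture of cells or the signal of the arrays was not tested. In the text, log2 fold changes carry the limma standard error, and each group has n = 4.

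Atf5 itself was checked first, since the labels call it the target. Its probe set read 8.57 ± 0.10 (SD, n = 4) on the log2 scale in control cells with vehicle and 8.35 ± 0.06 (SD, n = 4) in knockdown cells. With MG132 it read 8.77 ± 0.10 (SD, n = 4) in control and 8.46 ± 0.03 (SD, n = 4) in knockdown cells. Atf5 was thus lower in the knockdown line, by a log2 difference of -0.22 ± 0.05 with vehicle (a change of -14.0%, limma adjusted p = 0.00321) and of -0.31 ± 0.05 with MG132 (-19.3%, limma adjusted p = 0.000148). The 4 knockdown arrays lay below the 4 control arrays in both treatments (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 arrays can give). MG132 raised Atf5 in control cells by 0.20 ± 0.05 (limma adjusted p = 0.00759), where the exact permutation p was 0.0571. In knockdown cells its change of 0.10 ± 0.05 did not pass (limma adjusted p = 0.134, exact permutation p = 0.0286), and the difference of the responses was -0.09 ± 0.08 (limma adjusted p = 0.509). Without 4 arrays toward the low end of the within-group gradient (control vehicle 1 and 4, knockdown vehicle 1, control MG132 4), chosen after seeing the data, the difference with vehicle was -0.12 and missed the threshold (limma adjusted p = 0.0511). Control vehicle 4 (score -4.266) and knockdown MG132 2 (-4.269) lay almost level on the gradient, and with the latter left out in place of the former, the difference was -0.17 and passed (limma adjusted p = 0.0126), so the loss rests on that choice. Control vehicle 1 and 4 held the highest Atf5 values of their group (8.68 and 8.62). Of all genes, 74.3% with vehicle and 83.9% with MG132 had line differences smaller in size than that of Atf5, and the part of the transcript that its probe set reads, relative to the target of the hairpin, is not given in the sources used here.

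The first comparison asks what proteasome inhibition did to control cells. MG132 raised Slc7a11, a subunit of the cystine-glutamate exchanger, 10.1-fold (log2 fold change 3.34 ± 0.04, limma adjusted p = 2.53e-18). Hspa1a, the inducible cytosolic heat shock protein, rose 9.75-fold on its own probe set (3.29 ± 0.06) and by 2.46 ± 0.04 on a probe set shared with Hspa1b. Ddit3, which encodes the stress transcription factor CHOP, rose by 2.38 ± 0.04, and Atf3, another stress-induced factor, rose 5.14-fold (log2 fold change 2.36 ± 0.04). Hmox1, the inducible heme oxygenase, rose 4.94-fold (2.31 ± 0.04) and Gadd45a, a growth arrest gene, rose 4.59-fold (2.20 ± 0.03). Edn1, the precursor of the vasoconstrictor endothelin, fell by 2.15 ± 0.04 on the log2 scale, and Egr1, an immediate early transcription factor, fell by 1.42 ± 0.05.

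Others among the 10 largest increases were Prl2c5 (log2 fold change 3.34 ± 0.09), the chemokines Cxcl10 (2.54 ± 0.07) and Ccl2 (2.17 ± 0.05), and Osgin1 (2.16 ± 0.04). The other largest decreases were in the tight junction gene Cldn1 (-1.92 ± 0.13), Mycn (-1.74 ± 0.07), the matrix protease Adamts5 (-1.65 ± 0.06), Prss23 (-1.55 ± 0.04), Arsj (-1.49 ± 0.04), Medag (-1.47 ± 0.14), the potassium channel subunit Kcnf1 (-1.42 ± 0.08) and Cyp1b1 (-1.34 ± 0.04). Of the stress panel, Trib3 rose by 1.77 ± 0.04, Pmaip1, a death-promoting BCL2-family member, by 0.88 ± 0.09, Hspa5, the main chaperone of the endoplasmic reticulum, by 0.59 ± 0.03, Atf4 by 0.32 ± 0.03 and the proteasome subunit gene Psmd12 by 0.26 ± 0.03 (limma adjusted p between 7.86e-06 and 1.29e-15).

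Of the 18 pathway lists, 10 moved up and 1 moved down by camera. All 20 measured cytosolic heat shock chaperone genes rose (20 also adjusted over the list alone; camera adjusted p = 1.1e-17), among them Hspb1 (1.91 ± 0.05), Dnajb1 (1.27 ± 0.03) and Hsph1 (1.23 ± 0.03). ATF4 and CHOP stress regulators rose in 17 of 19 (17 adjusted over the list alone; camera adjusted p = 2.24e-16), including Ppp1r15a (1.71 ± 0.04), which directs dephosphorylation of the translation factor that stress kinases target. Genes of amino acid synthesis and transport rose in 18 of 21 (18 adjusted over the list alone; camera adjusted p = 6.97e-14). The glycine transporter Slc6a9 (1.30 ± 0.03) and the alanine transaminase Gpt2 (1.17 ± 0.04) were among these. NRF2 antioxidant genes rose in 18 of 22 (18 adjusted over the list alone; camera adjusted p = 5.82e-14). Nqo1 (1.74 ± 0.05) and Srxn1 (1.72 ± 0.04) were among them. Proteasome subunit genes rose in 28 of 33 (28 adjusted over the list alone; camera adjusted p = 5.82e-14), by less per gene: Psmd4 by 0.60 ± 0.03, Psmd11 by 0.48 ± 0.03 and Psmc4 by 0.42 ± 0.03. Ubiquitin and autophagy genes rose in 15 of 18 (16 adjusted over the list alone; camera adjusted p = 1.41e-10). Zfand2a (1.21 ± 0.03), the autophagy receptor Sqstm1 (1.18 ± 0.03) and Ufd1 (0.71 ± 0.04) were examples.

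Of 23 genes for chaperones and degradation factors of the endoplasmic reticulum, 17 rose and 1 fell (17 and 2 adjusted over the list alone; camera adjusted p = 3.82e-07), with Dnajb9 at 0.99 ± 0.06, Herpud1 at 0.89 ± 0.04 and Dnajc3 at 0.59 ± 0.03. Cytosolic tRNA synthetases rose in 12 of 18 (12 up and 1 down adjusted over the list alone; camera adjusted p = 8.78e-06, adjusted p = 0.0611 with an estimated correlation). Cars (0.63 ± 0.03) and Tars (0.50 ± 0.03) were among these. NF-kappaB cytokine genes rose in 9 and fell in 2 of 19 (9 and 2 adjusted over the list alone; camera adjusted p = 0.000383). Ccl5 (1.74 ± 0.05) and Nfkb2 (0.88 ± 0.03) were among them. Interferon-stimulated genes rose in 8 and fell in 1 of 19 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00637, adjusted p = 0.171 with an estimated correlation). Ifit1 (1.23 ± 0.09) and Oasl1 (0.84 ± 0.06) were examples. Extracellular matrix genes fell in 15 and rose in 2 of 24 (16 and 2 adjusted over the list alone; camera adjusted p = 7.53e-06): Thbs1 (-1.30 ± 0.03) and Ccn2 (-0.92 ± 0.04) fell, while Timp3, an inhibitor of matrix proteases, rose (1.30 ± 0.04). Fibroblast markers fell in 5 and rose in 1 of 10 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0165, 0.0581 over genes above the 25th percentile, and adjusted p = 0.0672 with an estimated correlation), with Col1a2 at -0.76 ± 0.05, Col1a1 at -0.68 ± 0.04 and S100a4 at -0.65 ± 0.04 against Pdgfra at 0.70 ± 0.05. The lists of DNA replication, mitosis, cholesterol synthesis, immediate early genes, p53 targets, BCL2 family and mitochondrial chaperones did not pass (camera adjusted p 0.0999 to 0.902), nor did the other 7 cell type lists (0.215 to 0.783). Single members of these still changed, such as Bcl2 (-1.01 ± 0.04), Bcl2l1 (-0.71 ± 0.04) and the mitochondrial protease Lonp1 (0.64 ± 0.04). Without control MG132 array 4 the p53 list passed (camera adjusted p = 0.0303), and with quantile normalization again and median centring it passed too (0.0391 and 0.0408), as it did with knockdown MG132 2 among the 4 arrays left out (0.046).

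In all, 7137 of 19938 genes changed at a false discovery rate of 5% (limma), 3341 higher and 3796 lower, of which 61 and 67 by 2-fold or more. With each array centred on its median, which moves the median of all genes by -0.05, the split was 2150 higher and 4624 lower. With every probe set it was 5204 higher and 4782 lower, and with the gradient as a covariate, which favours more calls, 4358 and 4217. Without the 4 arrays named above 6529 genes passed, 3259 higher and 3270 lower.

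The second comparison gives the MG132 response of the Atf5-knockdown cells. Slc7a11 rose 5.27-fold (log2 fold change 2.40 ± 0.04, limma adjusted p = 1.81e-16), Gadd45a 5.12-fold (2.35 ± 0.03), Atf3 4.57-fold (2.19 ± 0.04), Hmox1 4.54-fold (2.18 ± 0.04) and Ppp1r15a 4.18-fold (2.06 ± 0.04). Ddit3 rose 3.51-fold (1.81 ± 0.04). Hspa1a rose 1.79-fold on its own probe set (0.84 ± 0.06) and by 2.29 ± 0.04 on the probe set shared with Hspa1b. Egr1 had the largest decrease, to a level 4.77-fold lower (-2.25 ± 0.05), followed by Tmem119, a transmembrane protein gene, 3.53-fold lower (-1.82 ± 0.09).

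Also among the 10 largest increases were Prl2c5 (2.19 ± 0.09), Osgin1 (2.11 ± 0.04), the antiviral gene Rsad2 (2.00 ± 0.08) and Serpinb9e (1.82 ± 0.13). The remaining large decreases were in Adamts5 (-1.64 ± 0.06), the adhesion gene Amigo2 (-1.64 ± 0.04), the atypical cadherin Fat4 (-1.59 ± 0.05), Sh2d1b1 (-1.58 ± 0.11), Rab7b (-1.49 ± 0.10), Apln (-1.43 ± 0.06), Arhgap18 (-1.40 ± 0.07) and Lect2 (-1.40 ± 0.05). Trib3 rose by 1.40 ± 0.04, Hspa5 by 0.69 ± 0.03, Atf4 by 0.36 ± 0.03, Pmaip1 by 0.33 ± 0.09 and Psmd12 by 0.28 ± 0.03 (limma adjusted p between 0.00479 and 5.49e-14).

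Of the pathway lists, 10 moved up and 3 moved down. Heat shock chaperone genes rose in 20 of 20 (20 adjusted over the list alone; camera adjusted p = 4.41e-16). Hspb1 (1.40 ± 0.05), Hsph1 (1.06 ± 0.03) and the co-chaperone Bag3 (1.06 ± 0.05) were among these. Proteasome subunit genes rose in 32 of 33 (32 adjusted over the list alone; camera adjusted p = 5.71e-16), with Psmd11 at 0.58 ± 0.03 and Psmd4 at 0.56 ± 0.03. ATF4 and CHOP stress regulators rose in 16 of 19 (16 adjusted over the list alone; camera adjusted p = 1.8e-15) and NRF2 antioxidant genes in 18 of 22 (18 adjusted over the list alone; camera adjusted p = 7.5e-14). Srxn1 (1.27 ± 0.04) and Blvrb (0.92 ± 0.04) were among them. Amino acid genes rose in 18 of 21 (19 adjusted over the list alone; camera adjusted p = 1.6e-13). Slc6a9 (1.08 ± 0.03) and the neutral amino acid transporter Slc1a4 (1.05 ± 0.04) were examples. Endoplasmic reticulum chaperone genes rose in 20 of 23 (20 adjusted over the list alone; camera adjusted p = 8.83e-11). Dnajb9 (1.12 ± 0.06) and Herpud1 (0.98 ± 0.04) were among these. Ubiquitin and autophagy genes rose in 14 and fell in 1 of 18 (14 and 1 adjusted over the list alone; camera adjusted p = 1.12e-07). Sqstm1 (1.04 ± 0.03) and Zfand5 (0.83 ± 0.04) were among them. For tRNA synthetases the counts were 15 up and 1 down of 18 (16 and 1 adjusted over the list alone; camera adjusted p = 1.12e-07), with Wars at 0.56 ± 0.03 and Cars at 0.54 ± 0.03. NF-kappaB cytokine genes rose in 9 and fell in 3 of 19 (9 and 3 adjusted over the list alone; camera adjusted p = 0.00166). Cxcl10 (1.61 ± 0.07), Ccl5 (1.33 ± 0.05) and Ccl2 (0.55 ± 0.05) were examples.

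Cholesterol synthesis genes rose in 12 and fell in 3 of 19 (13 and 3 adjusted over the list alone; camera adjusted p = 0.00192, adjusted p = 0.26 with an estimated correlation): Insig1, a brake on sterol synthesis, rose by 0.77 ± 0.06 and Cyp51 by 0.73 ± 0.05, while Dhcr7, the last enzyme of the pathway, fell by 0.77 ± 0.05. DNA replication genes fell in 17 and rose in 1 of 25 (17 and 1 adjusted over the list alone; camera adjusted p = 0.000158, adjusted p = 0.12 with an estimated correlation). Ccne1 (-0.90 ± 0.04) and the ribonucleotide reductase subunit Rrm2 (-0.45 ± 0.03) were among these. Mitosis genes fell in 12 and rose in 1 of 21 (13 and 1 adjusted over the list alone; camera adjusted p = 0.000758, adjusted p = 0.158 with an estimated correlation). Ccnb2 (-0.38 ± 0.03) and Cenpa (-0.36 ± 0.03) were among them. Matrix genes fell in 12 and rose in 5 of 24 (12 and 7 adjusted over the list alone; camera adjusted p = 0.0474, adjusted p = 0.26 with an estimated correlation), with Thbs1 at -0.87 ± 0.03, Col1a2 at -0.72 ± 0.05 and Timp3 at 1.38 ± 0.04. The matrix call was lost without any of 7 single arrays, control vehicle 2 or 3, knockdown vehicle 1 or 2, control MG132 2, or knockdown MG132 1 or 4 (camera adjusted p 0.0503 to 0.0614). It was lost as well with quantile normalization again, median centring, the filters at the 25th percentile and at a mean of 6, without either set of 4 arrays and with the gradient as a covariate (camera adjusted p 0.053 to 0.124). Immediate early genes, p53 targets, interferon-stimulated genes, mitochondrial chaperones and the BCL2 family did not pass (camera adjusted p 0.0623 to 0.506), nor did any of the 8 cell type lists (0.0864 to 0.428), although Bcl2 itself fell by 1.17 ± 0.04. Without knockdown vehicle array 4 or knockdown MG132 array 1 the immediate early list passed (camera adjusted p 0.0484 to 0.049), and so it did with quantile normalization again, median centring and the filter at the 25th percentile (0.0239 to 0.0477). The p53 list passed with quantile normalization again and median centring (0.0239 and 0.0376), and the fibroblast markers with every probe set (0.01).

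In total 8124 genes changed (limma, false discovery rate 5%), 3276 higher and 4848 lower, with 49 and 85 by 2-fold or more. Median centring, which moves the median of all genes by -0.06, gave 1833 higher and 5795 lower. Array weights gave 5425 higher and 5264 lower. Without the 4 arrays, 10583 genes passed, 5498 higher and 5085 lower, and with knockdown MG132 2 left out in place of control vehicle 4 there were 4329 higher and 4858 lower.

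**Figure D1:**
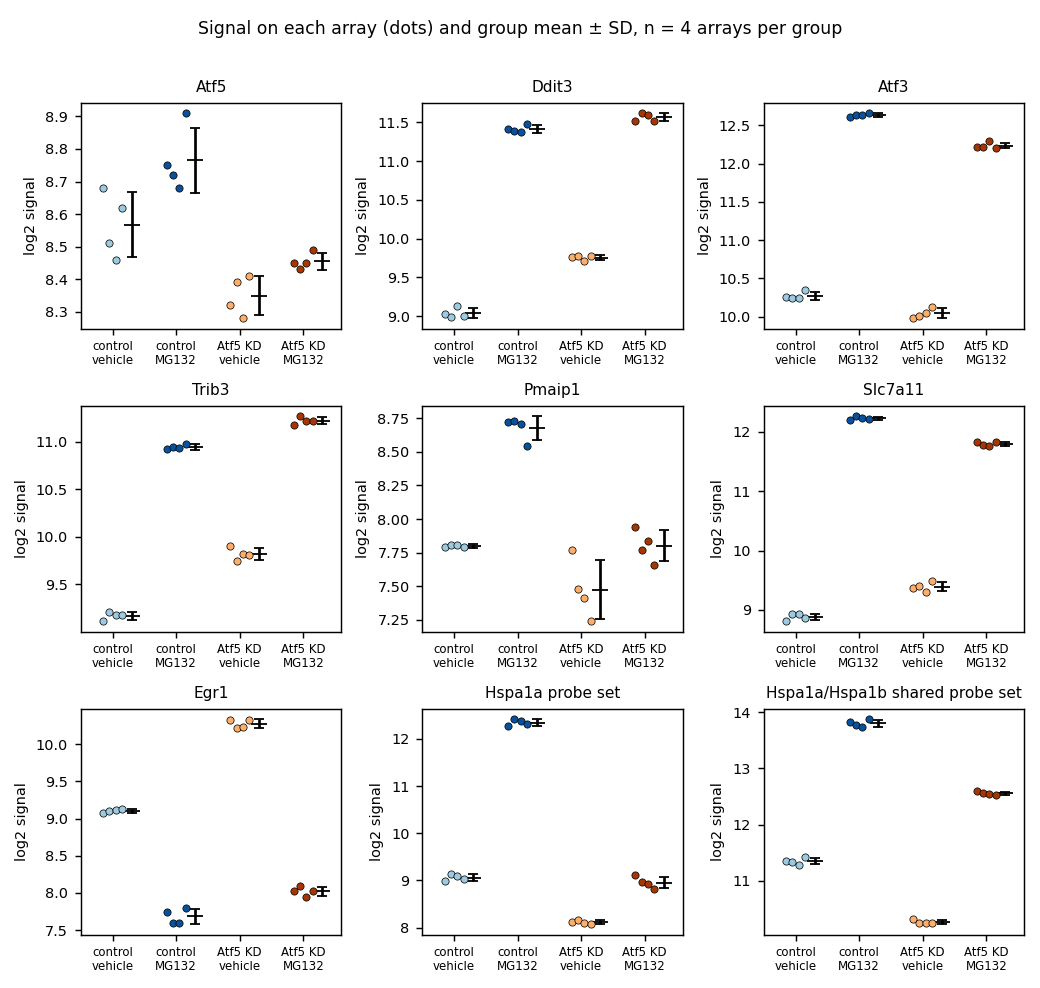
Log2 signal of 8 genes and of the probe set shared by Hspa1a and Hspa1b on each array (dots), with the mean and SD of each group of n = 4 (bars); columns are control and knockdown cells with vehicle and MG132. Atf5 lies between 8.28 and 8.91 on all 16 arrays, while Hspa1a on its own probe set goes from 9.06 to 12.35 in control cells and from 8.12 to 8.96 in knockdown cells.

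Both lines thus raised chaperone, proteasome, amino acid and antioxidant genes with MG132. Across all 19938 genes the responses correlated with a Pearson r of 0.758 and a Spearman rho of 0.635, where genes are not independent replicates. Of 5228 genes called in both, 1905 were higher in both, 3115 lower in both and 208 opposite, against 549 and 923 shared by chance in lists of these sizes. A line through 0 over the genes called in both had a slope of 0.915, knockdown on control. These contrasts share no array.

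**Figure D2:**
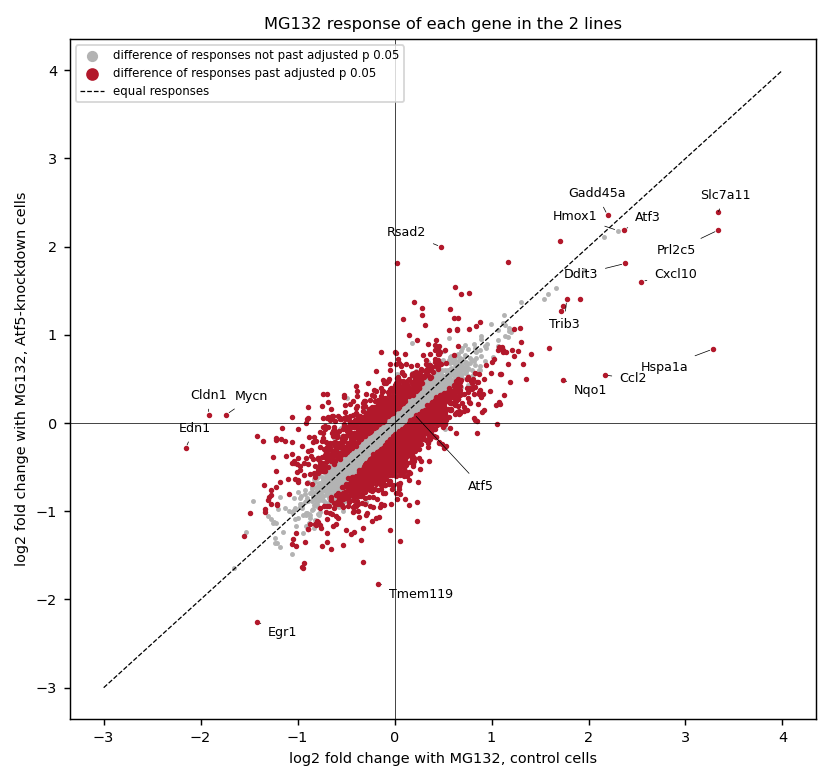
MG132 log2 fold change of each of 19938 genes in control cells (horizontal) and in Atf5-knockdown cells (vertical), with the dashed line where both are equal and in red the 2903 genes whose responses differed (limma adjusted p under 0.05 in the interaction). Slc7a11 lies at 3.34 and 2.40, Hspa1a on its own probe set at 3.29 and 0.84.

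The third comparison sets knockdown against control cells without MG132. Cd34, a cell surface sialomucin, was 40.6-fold higher in the knockdown line (log2 difference 5.34 ± 0.10, limma adjusted p = 1.44e-16). The homeobox gene Hoxc8 was 20.1-fold higher (4.33 ± 0.11), the receptor ligand Gas6 17.8-fold (4.15 ± 0.06) and Eng, a TGF-beta co-receptor, 14.2-fold (3.83 ± 0.08). The endocytic receptor gene Lrp2 was 23.1-fold lower (-4.53 ± 0.05) and the transcription factor gene Pax8 17.6-fold lower (-4.14 ± 0.07). Kcnip1, a potassium channel partner (-5.00 ± 0.09, limma adjusted p = 1.63e-16), Cldn1 (-4.96 ± 0.13), Nrn1 (-4.58 ± 0.09) and the T-box gene Tbx20 (-3.95 ± 0.11) were lower too, and the matrix gene Efemp1 (4.55 ± 0.06) and Tfpi, an inhibitor of coagulation (3.80 ± 0.06), were higher. Their lower group means, 6.06 to 6.24 in knockdown cells for the first 4 and 6.32 and 6.33 in control cells for the others, lay under the highest 25th percentile of the arrays, as did Cxcl5 below (6.19 in control cells). Such a level is not shown to be above background, so the size and rank of these differences depend on it.

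Also among the 10 highest were Tmem176b (4.36 ± 0.07), Psca (4.31 ± 0.09), the interleukin receptor gene Il13ra1 (4.01 ± 0.08) and Tmem176a (3.96 ± 0.09). The other lowest were the lysosomal protease Ctsh (-4.03 ± 0.06), Miga1 (-3.89 ± 0.10), Prxl2a (-3.73 ± 0.07) and the imprinted gene Peg3 (-3.68 ± 0.07). Of the stress panel, Egr1 (1.17 ± 0.05), Ddit3 (0.72 ± 0.04), Trib3 (0.65 ± 0.04), Hmox1 (0.27 ± 0.04) and Atf4 (0.23 ± 0.03) were higher in knockdown cells (limma adjusted p between 1.31e-05 and 3.11e-12). Hspa1a (-0.94 ± 0.06; log2 means of 11.35 and 10.26 in control and knockdown on the probe set shared with Hspa1b), Pmaip1 (-0.33 ± 0.09) and Atf3 (-0.23 ± 0.04) were lower (limma adjusted p between 0.00488 and 2.86e-10). Hspa5 differed by 0.01 ± 0.03 (limma adjusted p = 0.805). Psmd12 differed by -0.09 ± 0.03 (limma adjusted p = 0.0516) and passed without control vehicle 1, knockdown vehicle 4, control MG132 4 or knockdown MG132 1 (limma adjusted p 0.0263 to 0.0491), with either filter and with the gradient as a covariate (0.0183 to 0.0396). The covariate setting favours more gene calls.

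Of the pathway lists, 5 were higher in knockdown cells and 0 were lower. NF-kappaB cytokine genes were higher in 13 and lower in 1 of 19 (13 and 1 adjusted over the list alone; camera adjusted p = 9.37e-08), led by the adhesion molecule Vcam1 (3.46 ± 0.06), Ccl2 (3.18 ± 0.05), Cxcl5 (2.17 ± 0.06) and Ccl5 (1.72 ± 0.05). ATF4 and CHOP stress regulators were higher in 13 and lower in 2 of 19 (13 and 2 adjusted over the list alone; camera adjusted p = 1.29e-05). Nupr1 (1.28 ± 0.03) and Chac1 (0.81 ± 0.04) were examples. DNA replication genes were higher in 20 and lower in 2 of 25 (21 and 2 adjusted over the list alone; camera adjusted p = 1.93e-06, adjusted p = 0.101 with an estimated correlation), with small sizes, Cdt1 at 0.54 ± 0.04, Ccne1 at 0.52 ± 0.04 and Mcm6 at 0.41 ± 0.03. Interferon-stimulated genes were higher in 11 and lower in 1 of 19 (11 and 1 adjusted over the list alone; camera adjusted p = 7.47e-05, adjusted p = 0.101 with an estimated correlation). Ddx58, a sensor of viral RNA (1.61 ± 0.05), Ifit1 (1.61 ± 0.09) and Oasl2 (1.55 ± 0.09) were among these. Amino acid genes were higher in 13 and lower in 5 of 21 (13 and 5 adjusted over the list alone; camera adjusted p = 0.00587, adjusted p = 0.301 with an estimated correlation). Cth (0.89 ± 0.05) and Gpt2 (0.79 ± 0.04) were among them. The other 13 pathway lists, those of heat shock, endoplasmic reticulum, mitochondrial chaperones, proteasome, ubiquitin, NRF2, tRNA synthetases, p53, BCL2 family, immediate early genes, mitosis, cholesterol and matrix, did not pass (camera adjusted p 0.0936 to 0.816). With every probe set 5 of these passed, those of mitosis, tRNA synthetases, NRF2, ubiquitin and immediate early genes (camera adjusted p 0.021 to 0.0477). Members of the 13 lists differed singly, such as Nqo1 (3.37 ± 0.05), Gsta4 (2.78 ± 0.11), the basement membrane collagen Col4a1 (1.40 ± 0.04) and the matrix gene Tnc (-2.27 ± 0.05). None of the 8 cell type lists passed (camera adjusted p 0.266 to 0.71), while the keratin Krt19 (-2.44 ± 0.05), Tagln, a smooth muscle marker (-2.06 ± 0.06), Stmn2, a neuronal marker (-3.06 ± 0.10), Prrx1 (1.10 ± 0.03) and Thy1 (0.86 ± 0.05) differed as single genes.

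The test called 7848 genes (limma, false discovery rate 5%), 4283 higher and 3565 lower, and 390 and 230 by 2-fold or more. By chromosome, the median difference of the 10335 genes with a mean of at least 8 stood apart from that of other genes by 0.188 on chromosome 15, by 0.176 on chromosome 3 and by -0.173 on chromosome 12. Without the 4 arrays, 7330 genes passed. The labels describe 1 cell population of each kind, so the difference holds for these lines and cannot be assigned to the hairpin from these arrays.

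**Figure D3:**
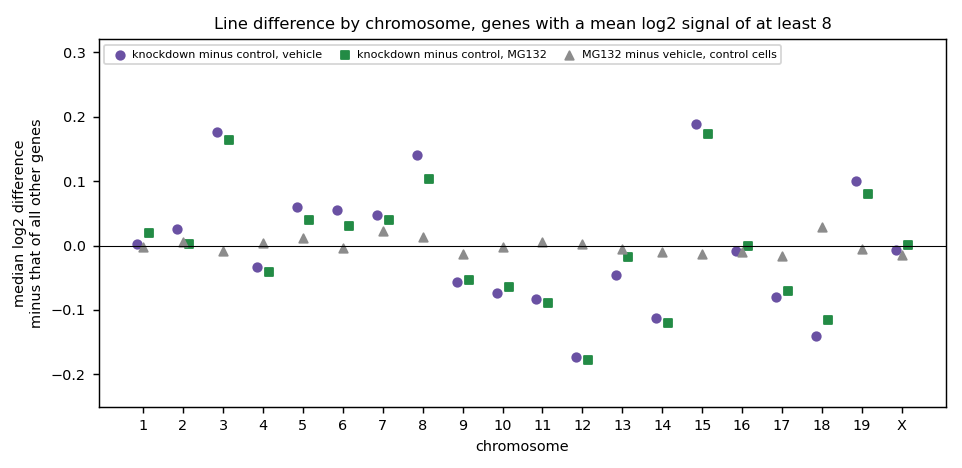
Median log2 difference of the genes on each chromosome minus that of all other genes, for genes with a mean log2 signal of at least 8: knockdown minus control with vehicle and with MG132, and MG132 minus vehicle in control cells. Chromosomes 15 and 3 lie highest and chromosome 12 lowest in both line comparisons, while no chromosome median in the control MG132 response is further than 0.028 from 0.

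The fourth comparison sets the lines side by side after MG132. Cd34 was 42.7-fold higher in knockdown cells (log2 difference 5.42 ± 0.10, limma adjusted p = 1.44e-16), and the interferon-inducible genes Ifi202b (4.51 ± 0.09) and Ifi203 (4.44 ± 0.11) were higher, from control means of 4.51 and 5.71. Tmem176b (4.25 ± 0.07), Efemp1 (4.01 ± 0.06), the alcohol dehydrogenase Adh7 (3.87 ± 0.07), Tmem176a (3.82 ± 0.09), Eng (3.61 ± 0.08), Tfpi (3.50 ± 0.06) and Apbb1ip (3.43 ± 0.13) followed. Pax8 was 20.2-fold lower (-4.33 ± 0.07), and Lrp2 17.1-fold lower (-4.09 ± 0.05), then Kcnip1 (-4.08 ± 0.09), Tbx20 (-3.85 ± 0.11), Miga1 (-3.78 ± 0.10), Ctsh (-3.70 ± 0.06), Fam110c (-3.67 ± 0.12), Nrn1 (-3.56 ± 0.09), Prxl2a (-3.52 ± 0.07) and Aff2 (-3.46 ± 0.11). The lower group means of Ifi202b, Ifi203, Efemp1, Tfpi, Kcnip1, Tbx20, Nrn1 and, below, Cxcl5, 4.51 to 6.34, lay under the highest 25th percentile of the arrays, so the size and rank of their differences depend on a level not shown to be above background.

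Hspa1a was 10.5-fold lower in knockdown cells under MG132 on its own probe set (-3.39 ± 0.06, limma adjusted p = 3.99e-17), with log2 means of 13.81 in control and 12.56 in knockdown cells on the probe set shared with Hspa1b. Pmaip1 (-0.87 ± 0.09) and Atf3 (-0.40 ± 0.04) were lower too, while Egr1 (0.34 ± 0.05), Trib3 (0.28 ± 0.04), Atf4 (0.27 ± 0.03), Ddit3 (0.15 ± 0.04), Hmox1 (0.14 ± 0.04) and Hspa5 (0.12 ± 0.03) were higher (limma adjusted p between 0.00474 and 1.54e-07). Psmd12 differed by -0.06 ± 0.03 and did not pass (limma adjusted p = 0.228).

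NF-kappaB cytokine genes were higher in 13 of 19 (13 adjusted over the list alone; camera adjusted p = 4.68e-09), with Vcam1 at 2.93 ± 0.06, Cxcl5 at 2.37 ± 0.06, Ccl2 at 1.56 ± 0.05 and Ccl5 at 1.31 ± 0.05. The ATF4 and CHOP list was higher in 15 and lower in 2 of 19 (15 and 2 adjusted over the list alone; camera adjusted p = 2.49e-06). Ppp1r15a (0.86 ± 0.04), Chac1 (0.69 ± 0.04) and Sesn2 (0.63 ± 0.04) were examples. Interferon-stimulated genes were higher in 12 and lower in 1 of 19 (12 and 2 adjusted over the list alone; camera adjusted p = 0.000249, adjusted p = 0.17 with an estimated correlation). Rsad2 (2.16 ± 0.08) and Oasl2 (1.80 ± 0.09) were among these. Amino acid genes were higher in 13 and lower in 2 of 21 (13 and 2 adjusted over the list alone; camera adjusted p = 0.00214, adjusted p = 0.262 with an estimated correlation): Cth (1.01 ± 0.05) was higher, while the transporters Slc7a3 (-1.38 ± 0.07) and Slc7a11 (-0.43 ± 0.04) were lower. DNA replication genes were higher in 14 and lower in 3 of 25 (15 and 3 adjusted over the list alone; camera adjusted p = 0.00597, adjusted p = 0.344 with an estimated correlation). Pola1 (0.50 ± 0.06) and Mcm6 (0.27 ± 0.03) were among them. Synthetases for tRNA were higher in 10 and lower in 4 of 18 (12 and 4 adjusted over the list alone; camera adjusted p = 0.024, adjusted p = 0.432 with an estimated correlation), with Farsb at 0.34 ± 0.03 and Kars at -0.34 ± 0.03, and this call was lost without control MG132 array 4 (0.071), with quantile normalization again and without either set of 4 arrays (0.0589 to 0.096). Heat shock chaperone genes were lower in 10 and higher in 2 of 20 (11 and 2 adjusted over the list alone; camera adjusted p = 0.0293, adjusted p = 0.344 with an estimated correlation): Dnaja4 (-0.68 ± 0.04) was lower, while Hspb8 (0.83 ± 0.05) and Hspa4l (0.82 ± 0.04) were higher. That call was lost without control MG132 array 3 or knockdown MG132 array 2 (0.051 to 0.0835) and over genes above the 25th percentile (0.0582). The other 11 pathway lists and the 8 cell type lists did not pass (camera adjusted p 0.152 to 0.944 and 0.264 to 0.976), though Nqo1 (2.12 ± 0.05) and Krt19 (-2.08 ± 0.05) differed.

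Under MG132 7588 genes differed (limma, false discovery rate 5%), 3536 higher and 4052 lower, and 286 and 197 by 2-fold or more; without the 4 arrays 8128 passed. The larger side turned with median centring (3708 higher and 3576 lower) and among changes of at least 1.5-fold (677 and 564). Across genes, the line differences with and without MG132 correlated at r = 0.901. Of 5689 genes called in both, 2814 were higher in both, 2680 lower in both and 195 opposite, against 760 and 725 shared by chance. These contrasts share no array.

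**Figure D4:**
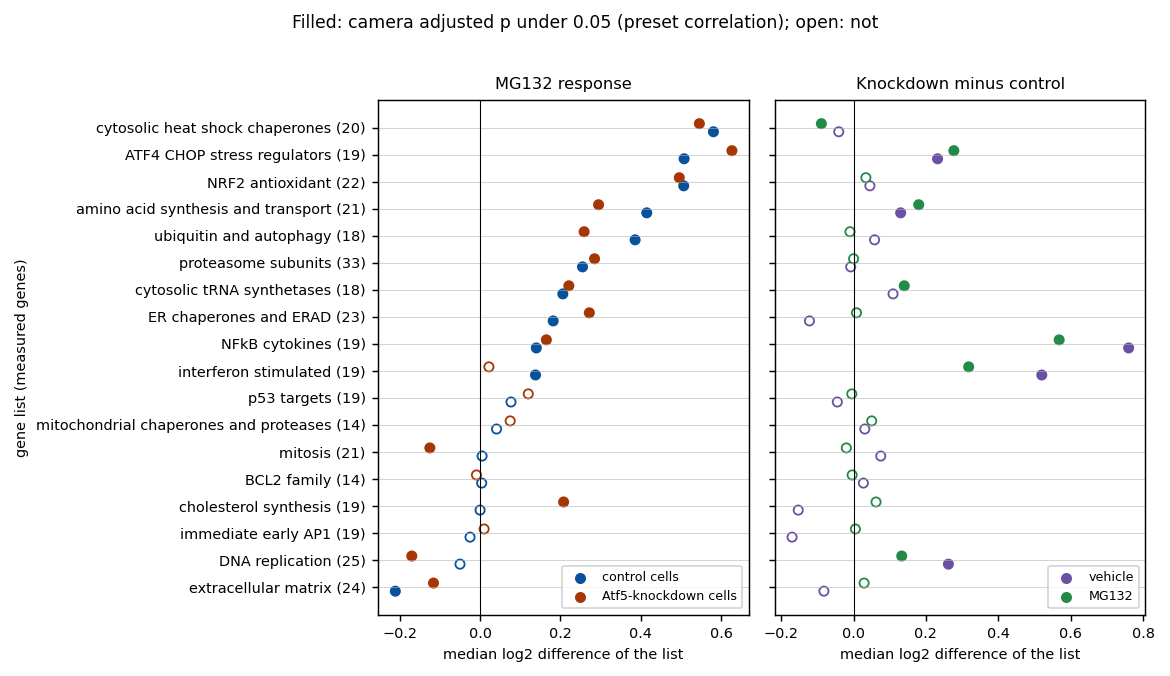
Median log2 change over the measured members of each of the 18 pathway lists: MG132 minus vehicle in each line (left) and knockdown minus control in each treatment (right); filled symbols passed camera at an adjusted p under 0.05, open ones did not. Heat shock chaperones lie at 0.58 in the control and 0.55 in the knockdown response, and NF-kappaB cytokine genes at 0.76 and 0.57 between the lines with vehicle and MG132.

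The last comparison follows the series title, which asks for genes whose response to proteasome inhibition depends on ATF5: the MG132 response in knockdown cells minus that in control cells. As the labels describe 1 cell population of each kind, a difference of the responses holds for these lines. It cannot be assigned to the hairpin or to Atf5 from these arrays. Among the genes that MG132 raised in control cells, several rose less in knockdown cells, with log2 differences of -1.62 ± 0.07 for Ccl2, -1.25 ± 0.07 for Nqo1, -0.94 ± 0.06 for Slc7a11, -0.94 ± 0.09 for Cxcl10 and -0.57 ± 0.06 for Ddit3 (limma adjusted p between 6.17e-06 and 8.1e-10). All of these began higher in knockdown cells, and all but Slc7a11 stayed higher with MG132. Ccl2 went from 12.5 to 13 there, against 9.3 to 11.4 in control cells, and Nqo1 from 11.6 to 12.1, against 8.2 to 9.9. Slc7a11 went from 9.4 to 11.8, against 8.9 to 12.2. Whether the higher start, or a compression of very bright probe sets, limited these rises was not tested. For Hspa1a the difference was -2.44 ± 0.08 on its own probe set (limma adjusted p = 7.55e-12) but -0.17 ± 0.05 on the probe set shared with Hspa1b (limma adjusted p = 0.0755). The latter value comes from a fit to all 35556 probe sets, where the own probe set had limma adjusted p = 4.16e-10. The shared probe set is not among the 19938 genes tested, so the 2 printed first are not adjusted over the same set. Edn1 (1.87 ± 0.06) and Mycn (1.83 ± 0.09), which MG132 lowered in control cells, had positive differences. With vehicle both already read lower in knockdown than in control cells, Edn1 at 9.15 against 10.25 and Mycn at 7.5 against 9.5. Cldn1 had one of 2.01 ± 0.18 but read only 6.17 and 6.26 in knockdown cells, under the 25th percentile of all arrays, where a decrease is hardly readable.

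Further positive differences were those of Ifi203 (1.79 ± 0.16), Rsad2 (1.52 ± 0.11), Kcnf1 (1.27 ± 0.12), Dusp4, a phosphatase of MAP kinases (1.16 ± 0.07), Wnt7b (1.13 ± 0.06), Brinp1 (1.10 ± 0.09) and Ifi202b (1.09 ± 0.13). Negative ones were those of Tmem119 (-1.65 ± 0.13), the matrix gene Aspn (-1.40 ± 0.26), Pxylp1 (-1.34 ± 0.10), Sh2d1b1 (-1.26 ± 0.15), Arrdc3 (-1.16 ± 0.08), Prl2c5 (-1.15 ± 0.13) and Hoxc8 (-1.12 ± 0.15). With vehicle, Kcnf1, Wnt7b and Brinp1 already read 6.9, 7.7 and 7.4 in knockdown cells, against 9.0, 9.1 and 9.6 in control cells. Tmem119, Pxylp1 and Hoxc8 read 7.9, 6.8 and 7.2 in control cells with vehicle, against 10.4, 8.9 and 11.5 in knockdown cells. Rsad2 and Dusp4, by contrast, rose more in knockdown cells. Whether a low start in 1 line limited the responses was not tested. Control means of Ifi203, Ifi202b, Aspn and Sh2d1b1, at 4.42 to 6.38, lay under the highest 25th percentile of the arrays, as did Aspn with MG132 in knockdown cells (5.40), so their sizes depend on levels not shown to be above background. Egr1 fell more in knockdown cells (-0.83 ± 0.07), and Pmaip1 (-0.55 ± 0.12) and Trib3 (-0.37 ± 0.05) rose less (limma adjusted p between 0.0053 and 9.94e-07). For Atf3 the difference of -0.17 ± 0.05 passed (limma adjusted p = 0.0419). It was lost without any of 12 single arrays: control vehicle 1, 2 or 3, knockdown vehicle 3 or 4, control MG132 1, 2, 3 or 4, or knockdown MG132 1, 2 or 4 (0.0555 to 0.0907). Quantile normalization again, median centring, every probe set and leaving out the 4 arrays with knockdown MG132 2 among them ended it too (limma adjusted p 0.0513 to 0.0954). Atf4 (0.03 ± 0.04), Psmd12 (0.03 ± 0.05), Hspa5 (0.10 ± 0.04) and Hmox1 (-0.12 ± 0.05) did not pass (limma adjusted p 0.12 to 0.767).

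Of the 18 pathway lists 5 had positive and 5 negative differences by camera, and 0 of these 10 passed with an estimated correlation. Immediate early genes were positive in 11 and negative in 2 of 19 (11 and 2 adjusted over the list alone; camera adjusted p = 1.23e-05, adjusted p = 0.127 with an estimated correlation). Mafk (0.54 ± 0.06), Ier3 (0.54 ± 0.07) and Klf6 (0.49 ± 0.05) were examples. Cholesterol synthesis genes were positive in 11 of 19 (11 up and 3 down adjusted over the list alone; camera adjusted p = 2.9e-05, adjusted p = 0.182 with an estimated correlation). Insig1 (0.49 ± 0.08), Msmo1 (0.43 ± 0.05) and Sqle (0.30 ± 0.05) were among these. Matrix genes were positive in 6 and negative in 1 of 24 (6 and 1 adjusted over the list alone; camera adjusted p = 8.26e-05, adjusted p = 0.127 with an estimated correlation). Ccn1 (0.69 ± 0.05), Ccn2 (0.52 ± 0.06) and Thbs1 (0.44 ± 0.05) were among them. Endoplasmic reticulum genes were positive in 4 and negative in 1 of 23 (4 and 1 adjusted over the list alone; camera adjusted p = 0.00212, adjusted p = 0.149 with an estimated correlation). Xbp1 (0.43 ± 0.07) and Sdf2l1 (0.35 ± 0.06) were examples. This call was lost without the 4 arrays with knockdown MG132 2 among them (camera adjusted p = 0.0685). Proteasome subunits were positive in 3 of 33, such as Psmd7 (0.31 ± 0.08), and in 0 adjusted over the list alone (camera adjusted p = 0.0483, adjusted p = 0.37 with an estimated correlation). The proteasome call was lost without any of 8 single arrays, control vehicle 2 or 3, knockdown vehicle 1, control MG132 1 or 4, or knockdown MG132 1, 3 or 4 (0.0516 to 0.226). Quantile normalization again, median centring, the filter at a mean of 6, every probe set, leaving out either set of 4 arrays and the gradient as a covariate ended it too (camera adjusted p 0.05 to 0.265).

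DNA replication genes had negative differences in 9 of 25 (13 adjusted over the list alone; camera adjusted p = 2.31e-05, adjusted p = 0.149 with an estimated correlation). Ccne1 (-0.34 ± 0.06), Cdt1 (-0.29 ± 0.06) and Cdc45 (-0.25 ± 0.04) were among these. Mitosis genes had them in 10 of 21 (10 adjusted over the list alone; camera adjusted p = 8.26e-05, adjusted p = 0.157 with an estimated correlation). Nusap1 (-0.40 ± 0.06) and Cenpf (-0.37 ± 0.07) were among them. Heat shock chaperone genes were negative in 7 and positive in 1 of 20 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0268, adjusted p = 0.292 with an estimated correlation). Dnaja4 (-0.54 ± 0.05) and Dnajb1 (-0.46 ± 0.05) were examples. This list had a median of 0.00 and a mean of -0.22, so that the median did not share the sign of the test, and its call was lost without Hspa1a (camera adjusted p = 0.138, mean -0.106), without control MG132 array 3 (0.0707), over genes above the 25th percentile (0.0738) and with the gradient as a covariate (0.0534). NF-kappaB cytokine genes were negative in 7 and positive in 2 of 19 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0313, adjusted p = 0.157 with an estimated correlation). The inhibitor gene Nfkbia (-0.65 ± 0.05) and Nfkb2 (-0.52 ± 0.05) were among these. Without control MG132 array 4 or knockdown MG132 array 4 this call was lost (0.0521 to 0.0968), as with the gradient as a covariate and without the 4 arrays with knockdown MG132 2 among them (0.0549 to 0.0703). Ubiquitin and autophagy genes were negative in 3 of 18 (4 adjusted over the list alone; camera adjusted p = 0.0358, adjusted p = 0.407 with an estimated correlation). Zfand2a (-0.39 ± 0.04) and Map1lc3b (-0.24 ± 0.05) were among them. That call was lost without any of 6 single arrays, control vehicle 1, knockdown vehicle 4, control MG132 2 or 3, or knockdown MG132 2 or 4 (0.0521 to 0.0755), and with median centring, the filters at the 25th percentile and at a mean of 6 and the gradient as a covariate (0.0501 to 0.0805). The lists of ATF4 and CHOP regulators, amino acid genes, NRF2, tRNA synthetases, mitochondrial chaperones, p53, BCL2 family and interferon-stimulated genes did not pass (camera adjusted p 0.113 to 0.745), nor did the 8 cell type lists (0.407 to 0.647). Among the ATF4, CHOP and amino acid genes Nupr1 (-0.65 ± 0.05) and Slc7a3 (-1.07 ± 0.09) had negative differences.

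In all 2903 genes had different responses (limma, false discovery rate 5%), 888 with a positive and 2015 with a negative difference, and 17 and 12 of them by 2-fold or more. Without the 4 arrays 2959 passed, 846 positive and 2113 negative, and of at least 1.5-fold there were 91 positive and 115 negative. Among the 3341 genes that MG132 raised in control cells, 783 had a negative difference: 399 of these were not called in knockdown cells, 240 rose in both lines and 144 fell in knockdown cells. Among genes that fell in control cells, 528 had a positive difference, which makes 1311 genes with opposite signs, against 606 with the same sign. The same-sign genes were 134 that rose and had a positive difference and 472 that fell and had a negative one. Independent lists of these sizes would share 338 and 169 genes of opposite sign and 149 and 384 of the same sign, so the genes that fell with a negative difference also exceeded that number. Both contrasts use the control arrays. Simulated unchanged genes shared a mean of 0.05 calls over 20 simulations, and 75% of all simulated genes had opposite signs, against 57.2% observed. With the control arrays split so that each contrast had its own, the opposite-sign overlap had a median of 637 (495 to 786 over 36 splits), made of 331 genes raised and negative, against 124 by chance, and 286.5 lowered and positive, against 80. The same-sign overlap then had a median of 248.5, with 66 genes raised and positive, against 65 by chance, and 182 lowered and negative, against 147. A further 986 genes had different responses without being called in control cells.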

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

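The tests of a compressed response, of splits after removal of the line and treatment effects, of the scaling between arrays and of chromosome medians in the MG132 responses were chosen only after the results they bear on had been seen, and so were leaving out either set of 4 arrays and reading the shares of negative differences by their exact intervals.

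The lines differed in 7848 genes without MG132, such as Cd34 at 5.34 and Lrp2 at -4.53. Endothelial cells mixed into the knockdown cultures are argued against by the endothelial markers, whose median difference was -0.095 (Pecam1 at log2 means of 6.87 in control and 6.76 in knockdown cells, Cdh5 at 7.59 and 7.32). Epithelial cells in the control cultures are argued against by a median of -0.096 over the epithelial markers (Krt8 at 8.42 and 8.51, Krt18 at 7.39 and 7.27), with Krt19 (-2.44) as the exception, and without detection calls it is open how many of these markers the fibroblasts themselves express. As a hypothesis, differences in chromosome copy number may contribute: the furthest chromosome median was 0.188 with vehicle (chromosome 15), and 3 chromosomes lay 0.15 or more away in both treatments. Of the 20 chromosomes, 15 passed in both treatments with one direction (random draws of genes, adjusted p under 0.05, genes treated as independent). The MG132 responses had no median further than 0.028 (control) and 0.047 (knockdown). The chromosome medians correlated at 0.989 between treatments, but line differences of single genes did so at 0.901, so any lasting difference of the lines could give this. Chromosome medians of up to 0.188 in size cannot by themselves give the differences of 10-fold or more. Copy number changes of single genes were not tested. Of the called genes, 92.1% differed by less than 2-fold. An effect of the hairpin stays open and untested. Of the origin of the lines, only position in the embryo (Hox genes, 0.447, open as a hypothesis) and sex (Y-linked genes, 0.02, argued against) were tested.

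Hspa1a rose by 3.29 in control and 0.84 in knockdown cells, a difference of -2.44. A general compression of the response is argued against as the whole of this difference: the slope over genes called in both lines predicts 3.007, the genes scatter about it with an SD of 0.203, and 0 of them lay further below it, although on the probe set shared with Hspa1b the slope predicts 2.25 and 2.29 was read. A lower heat shock response as a whole stays open: 9 of the 19 other chaperone genes that rose in control cells, 47.4% (exact 95% interval 24.4 to 71.1%), had a negative difference, 6 passed as negative and 1 as positive, and without Hspa1a the list did not pass (camera adjusted p = 0.138, and 0.429 with an estimated correlation). A fault of the Hspa1a probe set, such as a sequence difference between the lines under its probes, remains a candidate explanation, because the probe set shared with Hspa1b differed by only -0.165. That probe set also reads Hspa1b, so a change in Hspa1a alone could be hidden there, and a biological difference between the lines is not excluded.

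Of the 2903 genes with different responses, 2015 had a negative difference. Whether the within-group gradient is the whole cause was not decided. Negative calls made up 71.4% without 4 arrays toward its low end. They made up 69.5% with knockdown MG132 2 left out in place of control vehicle 4, which lay almost level with it. Scores on the gradient are deviations from each group's own mean. Leaving arrays out can therefore set the groups apart on it, so neither share decides. The scaling between arrays as the whole cause is argued against by 60.6% negative with quantile normalization again (exact 95% interval 58.8 to 62.5%), where it needs 45 to 55%. The share was 69.4% with the deposited values, so scaling may account for part of it. Median centring gave 71.2%, but it lowers the knockdown response (-0.06) more than the control response (-0.053). It thus shifts the differences toward negative and cannot argue against scaling. A shift of dim probe sets is argued against by the brightest of 3 equal sets of genes, where 62.4% were negative (exact 95% interval 59.8 to 64.9%, genes treated as independent) and the explanation needs 45 to 55%, although the dimmest genes, with 60.4% (53 to 67.5%, and 45.2% and 37.5% without either set of 4 arrays), do not by themselves exclude it, and genes of middle signal had 78.9%. A change of most genes in 1 direction, which RMA would hide, was not tested, and a biological difference between the lines is consistent with these values but was not tested apart from them.

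Other splits of the arrays were counted for each comparison. For the 4 comparisons of 4 against 4 arrays, 1 of 35 splits, the real one, gave as many genes as 7137, 8124, 7848 and 7588. The highest of the others gave 0, 0, 0 and 2. Every other split mixes the 2 groups, so their difference goes into its spread and lowers its count. These counts therefore rank the real split first, but do not show how many genes chance would call. That rank covers only these plates, whose spread may be technical. For the difference of the responses, 1 of 100 splits of the line labels within treatments gave as many as 2903, and the highest of the others gave 2512, but the lines differed in 7848 genes, which goes into the spread of every mixed split, so these splits decide nothing. With the line and treatment effects removed first, 1 of 100 splits, the real one, gave as many as 2903 and the highest of the others gave 0. The residuals still hold the difference of the responses, which goes into the spread of every mixed split. These counts therefore do not show how many genes chance would call either, and the rank holds only as far as residuals can be exchanged.

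The test of the difference of the MG132 responses (knockdown minus control) also marked 52 named genes, all given in the comparison of the responses; Cldn1, Ifi203, Ifi202b, Aspn and Sh2d1b1 rest on levels not shown to be above background. Cldn1 (2.01), Edn1 (1.87), Mycn (1.83), Ifi203 (1.79), Rsad2 (1.52), Kcnf1 (1.27), Dusp4 (1.16), Wnt7b (1.13), Brinp1 (1.10), Ifi202b (1.09), Ccn1 (0.69), Mafk (0.54), Ier3 (0.54), Ccn2 (0.52), Klf6 (0.49), Insig1 (0.49), Thbs1 (0.44), Msmo1 (0.43), Xbp1 (0.43), Sdf2l1 (0.35), Psmd7 (0.31) and Sqle (0.30) had positive log2 differences. Negative ones were those of Hspa1a (-2.44), Tmem119 (-1.65), Ccl2 (-1.62), Aspn (-1.40), Pxylp1 (-1.34), Sh2d1b1 (-1.26), Nqo1 (-1.25), Arrdc3 (-1.16), Prl2c5 (-1.15), Hoxc8 (-1.12), Slc7a3 (-1.07), Slc7a11 (-0.94), Cxcl10 (-0.94), Egr1 (-0.83), Nupr1 (-0.65), Nfkbia (-0.65), Ddit3 (-0.57), Pmaip1 (-0.55), Dnaja4 (-0.54), Nfkb2 (-0.52), Dnajb1 (-0.46), Nusap1 (-0.40), Zfand2a (-0.39), Trib3 (-0.37), Cenpf (-0.37), Ccne1 (-0.34), Cdt1 (-0.29), Cdc45 (-0.25), Map1lc3b (-0.24) and Atf3 (-0.17).

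In 30 of 604 groups of 4 arrays checked, over 151 named genes, a single array lay far from the other 3, with a gap to the nearest one above Dixon's 95% critical value as a share of the group's range. That is 4.97%, where chance gives 5%. The shares were, on control vehicle arrays, 1 for Psmd12, 0.867 for Pax8 and 0.889 for Mafk (array 1), 0.895 for Aff2 and 0.833 for Map1lc3b (array 2), 0.833 for Slc7a3 (array 3) and 0.857 for Psmc4 (array 4). On knockdown vehicle arrays they were 0.84 for Cldn1, 0.906 for Ifi203 and 0.889 for Psmd11 (array 1), 0.867 for Tfpi and 1 for Ufd1 (array 2), 0.875 for Mcm6 (array 3), and 0.833 for Oasl1, 0.864 for Cyp51 and 1 for Klf6 (array 4). Control MG132 arrays had 0.889 for Sh2d1b1 (array 1), 0.833 for Il13ra1 and 0.917 for Gpt2 (array 2), and 0.895 for Pmaip1, 0.857 for Ufd1, 0.933 for Zfand5, 0.906 for Oasl2 and 0.857 for Kars (array 4). Knockdown MG132 arrays had 0.889 for Col1a2 (array 1), 0.857 for Pdgfra (array 2), 0.875 for Atf3 and 0.875 for Col4a1 (array 3), and 1 for Dnajc3 and 1 for Cdc45 (array 4).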

How the results depend on the processing

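The settings without either set of 4 arrays and with the gradient as a covariate were chosen only after the data had been seen. The covariate comes from these same arrays, leaves the fold changes as they are and favours more gene calls. No called result changed sign in the settings run. A change of at least 1.5-fold left 719, 882, 1426, 1241 and 206 genes in the 5 comparisons, since most changes were smaller. Without the 4 arrays the Atf5 difference with vehicle was -0.125 (limma adjusted p = 0.0511), and with knockdown MG132 2 left out in place of control vehicle 4 it passed at -0.17 and the responses correlated at 0.717; the cause was not tested. With an estimated correlation 2 lists passed between the lines with vehicle, 2 with MG132 and 0 in the difference of the responses, since that test allows for correlated genes. With every probe set 10 lists passed between the lines with vehicle, and the responses correlated at 0.715, and with the gradient as a covariate 6 lists passed in the difference of the responses; the cause was not tested. With 1 array left out, genes changed ranged from 6368 to 7281, 7169 to 9396, 7303 to 8143, 7056 to 7757 and 2325 to 3387, lists from 11 to 12, 12 to 14, 5 to 5, 6 to 7 and 7 to 10, the Atf5 difference from -0.253 to -0.18 with vehicle and -0.338 to -0.262 with MG132, the correlation from 0.728 to 0.77 and the opposite-sign overlap from 1078 to 1479. It is open whether replicate numbers pair the arrays. The deviations of same-numbered pairs had a median correlation of 0.087, against -0.045 for other pairs from different groups. Of 24 same-numbered pairs (-0.501 to 0.396), 10 correlated above 0.1, and 8 of 16 arrays correlated best with their own number. With the replicate number as a block 7067, 8162, 7766, 7498 and 2668 genes changed, and the matrix list in the knockdown response and the proteasome list in the difference of the responses did not pass (camera adjusted p 0.0524 to 0.0546). Over all settings, 17 values of gene lists and 7 of named genes newly passed, and 82 and 16 no longer passed. No filter on signal over background could be used, since no detection calls were used here.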

Other observations

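The tests of Hox and imprinted genes were chosen only after the line differences had been seen; the test of Y-linked genes was not.

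Homeobox genes of the Hox clusters, which mark position along the body axis, differed between the lines without MG132. Of 37 measured, 21 were higher in knockdown cells, 6 were lower and 10 did not pass, and 13 differed by 2-fold or more. The Hoxc cluster led, with Hoxc8 at 4.33 ± 0.11, Hoxc6 at 3.62 ± 0.09, Hoxc9 at 2.92 ± 0.07 and Hoxc12 at 2.71 ± 0.07 (log2 difference ± SE, n = 4), and Hoxb13 (1.51 ± 0.07) and Hoxa10 (1.17 ± 0.10) were higher too. Hoxd8 (-3.42 ± 0.08) and Hoxd9 (-1.20 ± 0.07) were lower. Of 16 imprinted genes, a list chosen after the values of Peg3 were seen, 2 were higher and 8 lower: Peg3 (-3.68 ± 0.07), Grb10 (-2.85 ± 0.05), Peg10 (-0.88 ± 0.04), Phlda2 (-0.86 ± 0.06) and Ndn (-0.65 ± 0.09) were lower, and Mest (0.76 ± 0.07) was higher.

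A hypothesis is that the lines may come from cells of different position in the embryo, rather than differing by the hairpin alone. The median size of the log2 difference over the Hox genes was 0.447, against a median of 0.11 and a 95th percentile of 0.167 over 10000 random lists matched on mean expression, which is consistent with it. The Hox genes were tested because Hoxc8 had been seen among the largest differences, so the value cannot settle the hypothesis. A difference in the sex of the embryos is argued against by the Y-linked genes: their median size of difference was 0.02 over Eif2s3y, Kdm5d and Uty, at log2 means of 4.38 to 5.92 in control and 4.28 to 5.90 in knockdown cells, and Xist read 12.74 and 12.52.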
